A study of Mus musculus with 24 samples.

How the data were processed

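RNA of sorted LT-HSCs was measured by sequencing of polyadenylated RNA, per the labels from column-purified RNA of cells sorted after depletion of TER-119, Gr-1, CD11b, B220, CD3 and CD5 positive cells. The table holds expected counts per gene that, per the labels, the authors made with cutadapt, STAR 2.5.2a and RSEM 1.2.30 on GRCm38 before it was deposited. RSEM divides reads shared by several genes among them, so 16.8% of the values are not integers, and the values were rounded before testing. The annotation release is not stated. Reads were not available, so neither the mutation in Jak2 nor the strand of the reads was examined.

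The table has 38215 genes and 24 libraries in 4 groups of 6, and every sample column was used. Totals ran from 24.6 to 39.7 M. Reads of mitochondrial genes made up 1.54 to 4.01% and the 10 largest genes 3.89 to 5.16%. No libraries were identical (chi-square per degree of freedom from 7.1 to 71.92 between libraries of a group). Of the gene IDs, 36345 were in the supplied reference. Positions were those given in the table, and for 99.76% of the shared genes they overlapped the position in the reference.

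Genes were kept by filterByExpr with a minimum count of 10, which left 15879 genes and 99.95% of the counts and removed 22336. Main tests used edgeR 4.0.16 in R 4.3.3, with TMM factors, a design of 4 group means without a block, robust quasi-likelihood F tests and Benjamini-Hochberg adjustment over all genes. The common biological coefficient of variation was 18.6%. The 5 comparisons were pegIFN against vehicle in each genotype, Jak2V617F against wild-type in each treatment, and the interaction. CPM were computed with TMM-scaled library sizes, and log2 CPM for components and scores with a prior count of 2. Groups, comparisons, main test, lists, the rule for naming genes and most alternative analyses were fixed before the data were examined.

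Gene lists were written from general knowledge, 31 lists of 567 genes, of which 566 matched the table (7 by ID) and 544 were tested. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, for lists with at least 3 tested members, and adjusted over the lists. The preset correlation is small, so each call was set beside camera with an estimated correlation. Members are also counted after adjustment over the list alone.

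Named genes were chosen by rule: the 8 largest increases and 8 largest decreases among called genes with mean log2 CPM of at least 1, up to 4 members of each list with the smallest p, and a fixed set that included Bcl2l1, Bcl2, Mcl1, Bcl2l11, Bax, Bak1, Pmaip1, Bbc3, Jak2, Ifnar1, Cdkn1a, Ptprc and Xist. Some genes the rule selects are not reported. Genes named outside the rule were picked after their values were seen: Cd48, Slamf1, Procr, Hlf, Mecom, Fos, and, outside the comparisons in which the rule names them, Fgd5, Ifi27l1, Gbp4, Btg2, Trp53inp1, Gata2, Alas2, Eda2r, Klf1, Isg15, Car1 and Thbs1. The rule was not written for the fit with the mouse as a block, and its use there was chosen after the values were seen.

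The mouse of each library was read from the number in the library name, as the labels state no mouse directly. The labels have both genotypes in each recipient, so libraries of both genotypes with the same number were taken as the same mouse. As a check, the 12 pairs correlated at 0.12 to 0.42 (median 0.29) after group means were removed, and 10 of 12 were highest with their own partner. The library names carry 12 sample sheet positions, each shared by 2 libraries of the same group. If the libraries came in 2 sets, each held 3 libraries of every group, but the labels do not say which library was in which, so no term for the set was fitted. Fos in pegIFN mice and the vehicle G2/M gap split the mice in a way that such sets allow, and whether either split follows a set is open. Values from edgeR with the mouse as a block are given beside many of the genotype and interaction results.

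The alternative analyses fixed at that stage were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter of 1 CPM in 12 libraries, a fit of only the groups compared, the replicate number as a block, limma-voom with the mouse as a random block, 1 surrogate variable (sva 3.50.0), each library left out, and camera with an estimated correlation and fry for lists. Added after the data were seen were fits without the pair of libraries that stood apart on sex-linked genes or without their mice, alternatives of the overlap, the count of called genes near Ptprc, and exact permutations of the list means with the mouse as the unit. Group labels were also reassigned in up to 100 other splits. The pipeline was tested on simulated data: the main fit recovered 41.8 to 62.7% of added log2 changes of 0.5 and 83.3 to 95.5% of changes of 2, with 2.5 to 6.9% false calls. The simulated libraries were independent, without values shared by a mouse, and only a small share of the genes changed. These rates therefore need not hold for the real, paired libraries. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.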

Results

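Long-term haematopoietic stem cells (LT-HSCs) were profiled by sequencing of polyadenylated RNA in 24 libraries from 12 mice. The mice were lethally irradiated recipients that carried a mixture of wild-type and Jak2V617F bone marrow. Jak2V617F is an activating mutation of the cytokine receptor kinase Jak2 that drives myeloproliferative neoplasms (MPN). Lineage-negative Sca1+ cKit+ CD150+ CD48- cells of each mouse were sorted by donor marker into a wild-type library (CD45.1) and a Jak2V617F library (CD45.2). Vehicle was given to 6 mice and pegylated interferon alpha (pegIFN) to 6, at 600 ng per injection in 5 doses over 4 weeks, and the cells were taken 48 hours after the last dose. This gave 4 groups of 6 libraries, in which, by the numbers in the library names, each mouse contributed a library of both genotypes. Total counts per library ran from 27.1 to 35.7 M for wild-type vehicle and 30.2 to 39.7 M for wild-type pegIFN. They ran from 24.6 to 31.6 M for Jak2V617F vehicle and 28.8 to 34.3 M for Jak2V617F pegIFN. The title of the study names interferon-induced apoptosis and the inhibition of Bcl-xL, the product of Bcl2l1, and no library comes from a mouse given an inhibitor.

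Fold changes are given on the log2 scale with their standard error from the edgeR model, and levels are CPM (counts scaled to the size of the library) as mean ± SD over the 6 libraries of a group. A gene or list is called where its Benjamini-Hochberg adjusted p is under 0.05, and 15879 genes were tested. List results give the median log2 fold change of the members and the adjusted p of camera over 31 lists. Each list count is followed by the count adjusted over the list alone.

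The first principal component of log2 CPM held 43.5% of the variance and separated the treatments, with pegIFN libraries from -59.4 to -18.3 and vehicle libraries from 20.6 to 68.6. The second held 8.7%, and in each of the 12 mice the Jak2V617F library lay below its wild-type partner. Jak2 (ENSMUSG00000024789, chromosome 19, 29251828 to 29313080, GRCm38) was present in all groups, at 138 ± 16.7 CPM in wild-type vehicle and 156 ± 5.10 in wild-type pegIFN. It was at 119 ± 8.80 in Jak2V617F vehicle and 126 ± 9.39 in Jak2V617F pegIFN. Counts per gene do not resolve the point mutation, so these levels do not test the genotype.

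**Figure D1:**
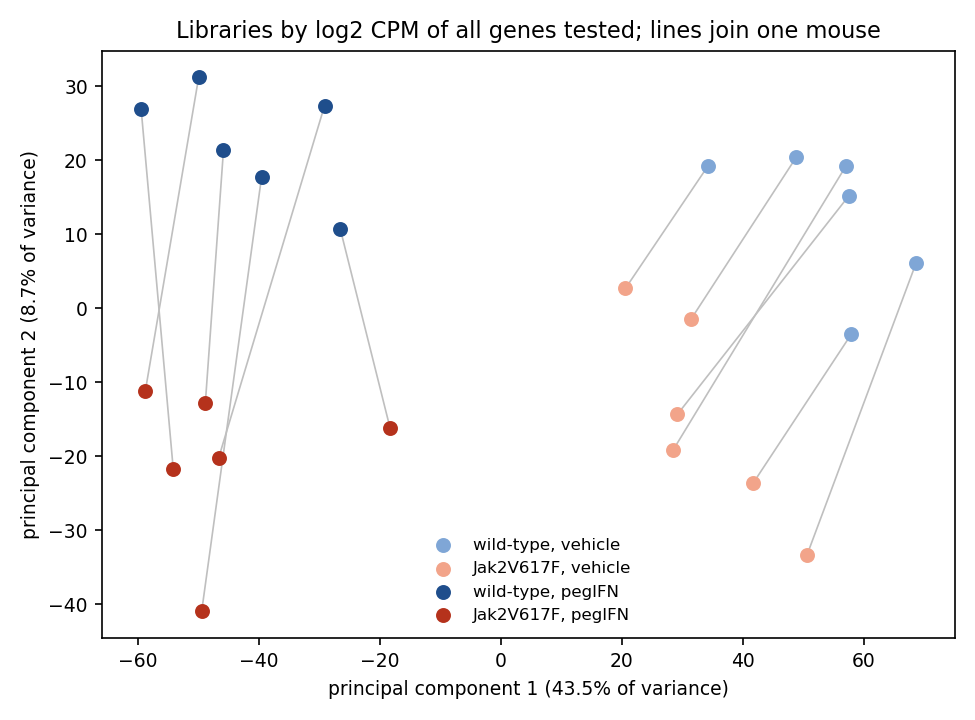
Principal components 1 and 2 of log2 CPM over all genes tested, as scores without a unit, with a point for each library coloured by group and lines joining the libraries of a mouse. The 12 pegIFN libraries lie at or below -18.3 and the 12 vehicle libraries at or above 20.6 on component 1, which holds 43.5% of the variance.

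Sex-linked genes differed between the donors. Xist (ENSMUSG00000086503, chromosome X, 103460375 to 103483217), the RNA that silences an X chromosome in female cells, ran at 2039 ± 864 CPM in wild-type vehicle and 2255 ± 283 in wild-type pegIFN. It was at 26.5 ± 17.1 in Jak2V617F vehicle and 172 ± 237 in Jak2V617F pegIFN. A pair of libraries stood apart from their groups. Wild-type vehicle replicate 4 had 599.8 CPM of Xist and Y-linked genes at 112.4% of the Jak2V617F vehicle mean, where the other 5 libraries of its group had 1937 to 3310 CPM and 9.1 to 34.1%. Jak2V617F pegIFN replicate 1 had 653.9 CPM of Xist and 67.2% for the Y-linked genes, where the other 5 had 40.8 to 110.1 CPM and 71.1 to 97.4%. In the other libraries Xist followed the genotype, and Y-linked genes were lower in each wild-type than in each Jak2V617F library. They were not absent from wild-type cells, with 9.1 to 34.1% in those 5 vehicle libraries and 1 to 10.2% under pegIFN. Fits without the pair of libraries keep this partial signal. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were called higher in Jak2V617F cells in 3 of 4 members under vehicle (4 adjusted over the list alone, median 1.36, adjusted p = 0.00047, and adjusted p = 0.335 with an estimated correlation). Under pegIFN all 4 were higher (4 adjusted over the list alone, median 3.65, adjusted p = 4.9e-17).

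**Figure D2:**
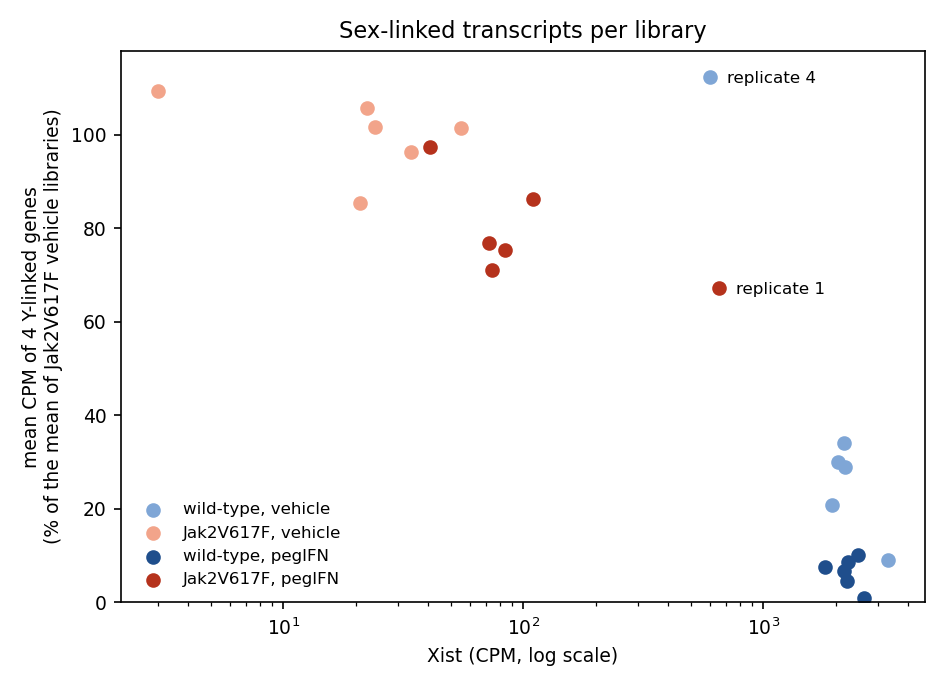
Xist in CPM (log scale) against the mean CPM of 4 Y-linked genes as a percent of the Jak2V617F vehicle mean, with a point for each library coloured by group. Wild-type vehicle replicate 4 (599.8 CPM, 112.4%) and Jak2V617F pegIFN replicate 1 (653.9 CPM, 67.2%) lie apart from the other libraries of their groups.

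The first comparison, pegIFN against vehicle in wild-type LT-HSCs, asks what repeated interferon does to normal stem cells. It gave the strongest signal in interferon-stimulated genes, the antiviral and signalling genes switched on by type I interferon. Of 52 measured, 51 rose and 1 fell (51 and 1 adjusted over the list alone), with a median of 2.65 (adjusted p = 1.6e-200). Ifi27l2a rose by 6.90 ± 0.15 (adjusted p = 8.4e-22). Mx1, a GTPase that restricts viruses, rose by 5.71 ± 0.27 (adjusted p = 7.4e-14) and Irf7, the transcription factor that amplifies the interferon response, rose by 5.33 ± 0.17 (adjusted p = 5.1e-18). Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), a ubiquitin-like modifier, went from 4.35 ± 0.754 to 190.1 ± 20.03 CPM (log2 5.45 ± 0.12, adjusted p = 4.6e-22). Ifi27l1 was the member that fell, by -0.70 ± 0.12 (adjusted p = 3.2e-05). Apol9b (5.74 ± 0.24, adjusted p = 3.2e-15) and Scin, an actin-severing protein (5.50 ± 0.59, adjusted p = 1.8e-07), were among the 8 largest increases of all genes.

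Related interferon programmes rose in wild-type cells as well. Of 16 interferon-inducible GTPases, 10 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.80, adjusted p = 0.00996, adjusted p = 0.676 with an estimated correlation and adjusted p = 0.0543 in the exact permutation of mice). Irgm1 was at 1.69 ± 0.16 among those that rose and Gbp4 at -1.51 ± 0.41 among those that fell. Of 19 genes of class I antigen presentation, 17 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.54, adjusted p = 3.2e-07, and adjusted p = 0.559 with an estimated correlation). Examples were H2-T22 (161 ± 25.4 to 369 ± 31.99 CPM), the peptide-loading protein Tapbp (0.99 ± 0.09) and the immunoproteasome subunit Psmb8 (0.67 ± 0.07). Reads of near-identical paralogs in these families are shared out by the authors' quantification, so single members are less certain than their group. Components of the receptor and JAK-STAT pathway went both ways, with 4 of 20 higher and 8 lower (5 and 8 adjusted over the list alone; median -0.14, adjusted p = 0.306). Ifnar1, a chain of the type I interferon receptor, fell by 0.42 ± 0.06 (adjusted p = 3.0e-06), Jak1 fell by 0.35 ± 0.05 (adjusted p = 1.3e-06), and Jak2 rose by 0.17 ± 0.07 (adjusted p = 0.034).

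Genes that set the threshold for mitochondrial apoptosis changed on both sides in wild-type cells. The effectors Bax (ENSMUSG00000003873, chromosome 7, 45461695 to 45466898) and Bak1, which open the outer mitochondrial membrane, rose from 35.0 ± 2.59 to 60.2 ± 2.56 CPM (log2 0.78 ± 0.07, adjusted p = 4.9e-09) and by 0.57 ± 0.06 (adjusted p = 2.9e-08). Bcl2l1 (ENSMUSG00000007659, chromosome 2, 152780668 to 152831728), which encodes Bcl-xL, rose from 52.5 ± 9.57 to 74.0 ± 7.60 CPM (log2 0.50 ± 0.11, adjusted p = 0.00061). The other main survival genes fell. Mcl1 (ENSMUSG00000038612, chromosome 3, 95658721 to 95663176) went from 390.1 ± 56.1 to 234 ± 31.3 CPM (log2 -0.74 ± 0.10, adjusted p = 1.3e-06). Bcl2 fell by 0.25 ± 0.08 (adjusted p = 0.0076). Among the other pro-apoptotic members, Bmf fell by 1.61 ± 0.34 (adjusted p = 0.00024) and Bcl2l11, which encodes Bim, fell by 0.32 ± 0.09 (adjusted p = 0.0031). Bbc3 (Puma, 0.19 ± 0.17, adjusted p = 0.35) and Pmaip1 (Noxa, -0.13 ± 0.32, adjusted p = 0.75) were not called. As lists, the pro-apoptotic family had 5 of 10 members higher and 2 lower (5 and 2 adjusted over the list alone; median 0.24, adjusted p = 0.205). The pro-survival family had 1 of 5 higher and 3 lower (1 and 3 adjusted over the list alone; median -0.25, adjusted p = 0.331). The exact permutation of mice, added after the data were seen, called both lists. It asks whether a list's mean differs at all between treatments, where camera compares the list with the other genes. Its calls therefore do not set these lists apart from other genes. The mean log2 CPM of the pro-apoptotic list differed by 0.11 (adjusted p = 0.0052) and that of the pro-survival list by -0.29 (adjusted p = 0.0089). The death receptor and caspase list had 8 of 27 higher and 8 lower (8 and 8 adjusted over the list alone; median 0.03, of unsteady sign between scalings, adjusted p = 0.428). Daxx rose by 1.79 ± 0.08 and the initiator Casp8 by 0.41 ± 0.05, and Cflar, an inhibitor of Casp8, fell by 0.47 ± 0.06.

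**Figure D3:**
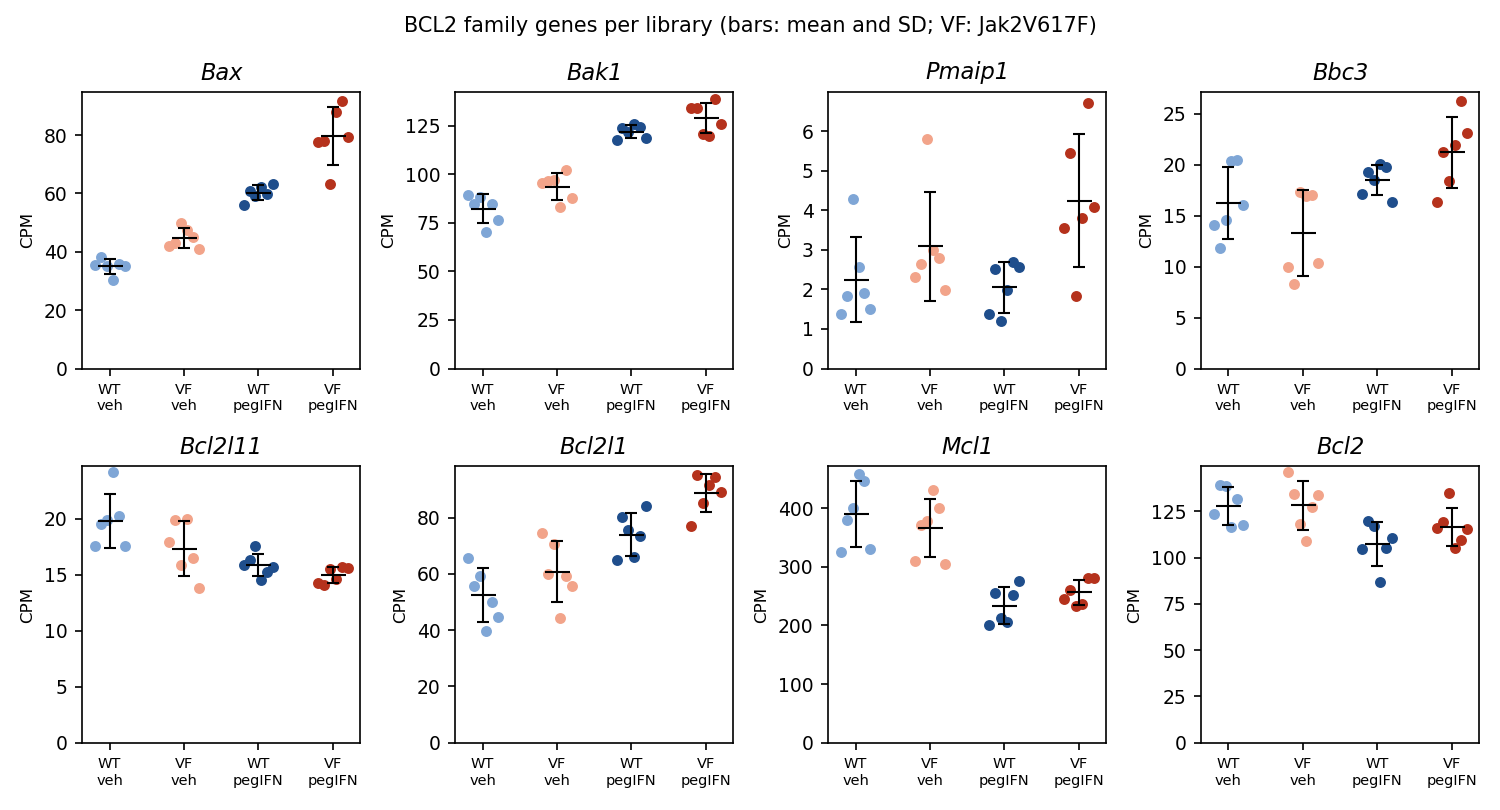
CPM of 8 BCL2 family genes, with a point for each library, coloured by group (VF, Jak2V617F; WT, wild-type), and bars at mean ± SD of 6 libraries. Bax rose with pegIFN from 35.0 to 60.2 CPM in wild-type and from 44.7 to 79.6 CPM in Jak2V617F cells, Bcl2l1 rose in both genotypes and Mcl1 fell in both.

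Cell cycle genes rose in wild-type cells. Of 21 genes of G1/S and DNA replication, 18 rose and none fell (18 and 0 adjusted over the list alone; median 0.44, adjusted p = 4.3e-05). The helicase subunits Mcm5 (0.65 ± 0.09) and Mcm6 (0.50 ± 0.07) and the licensing factor Cdt1 (0.67 ± 0.08) were among them. Of 22 genes of G2/M and mitosis, 18 rose and none fell (19 and 0 adjusted over the list alone; median 0.48, adjusted p = 0.00087). The mitotic kinase Plk1 (0.86 ± 0.16) and Ube2c (0.71 ± 0.12) were among them. DNA repair genes were higher in 15 of 22 and lower in none (16 and 0 adjusted over the list alone; median 0.29, adjusted p = 0.00996). The helicase Blm (0.79 ± 0.10) and Fanca (0.74 ± 0.13) were among them. With an estimated correlation these lists had adjusted p = 0.559 for G1/S, adjusted p = 0.656 for G2/M and adjusted p = 0.655 for DNA repair. Targets of p53, the transcription factor that answers DNA damage, were split in wild-type cells, with 6 of 20 higher and 4 lower (6 and 4 adjusted over the list alone; median 0.15, adjusted p = 0.187). Phlda3 (2.09 ± 0.31) and Aen (0.91 ± 0.08) rose, and Btg2 (-2.03 ± 0.52) and Trp53inp1 (-0.91 ± 0.19) fell. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090979 to 29100722), the inhibitor of cyclin-dependent kinases known as p21, was at 0.24 ± 0.32 (adjusted p = 0.54).

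Genes that mark long-term stem cells fell with pegIFN in the wild-type libraries. Of 23, 18 fell and 2 rose (18 and 2 adjusted over the list alone; median -0.95, adjusted p = 4.9e-07, and adjusted p = 0.359 with an estimated correlation). Sult1a1 fell by 4.14 ± 0.30 (adjusted p = 1.6e-10) and the self-renewal factor Meis1 fell by 0.60 ± 0.06 (adjusted p = 2.7e-08). Picked after their values were seen, Fgd5 fell by 2.45 ± 0.31, Hlf fell by 2.08 ± 0.27, Procr fell by 1.90 ± 0.30 and Mecom fell by 1.31 ± 0.19. The members that rose were Gata2 (0.28 ± 0.09) and Ly6a, which encodes the sorting antigen Sca-1 and is itself inducible by interferon (57.0 ± 11.3 to 228 ± 51.1 CPM, log2 2.00 ± 0.20, adjusted p = 2.9e-08). Cd48, the antigen whose absence defines the gate, also rose at the RNA level, from 7.80 ± 2.70 to 26.3 ± 6.45 CPM (log2 1.76 ± 0.19, adjusted p = 6.8e-08). Slamf1 (CD150) was at -0.19 ± 0.11 (adjusted p = 0.15). Both were picked after their values were seen. Regulators of quiescence fell in 12 of 16 and rose in none (12 and 0 adjusted over the list alone; median -0.58, adjusted p = 0.00087, and adjusted p = 0.294 with an estimated correlation). The cell cycle inhibitor Cdkn1c (-1.79 ± 0.22), Foxo1 (-0.63 ± 0.08) and Ndn (-2.41 ± 0.37) were among them.

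Lineage lists held members of both directions in wild-type cells. In the erythroid list, the regulator Klf1 rose from 20.3 ± 5.59 to 85.6 ± 23.8 CPM (log2 2.08 ± 0.25, adjusted p = 5.0e-07), the regulator Gata1 by 1.32 ± 0.15 (adjusted p = 2.4e-07) and the erythropoietin receptor Epor by 1.29 ± 0.10. Members that fell were the membrane transporter Slc4a1 (-5.12 ± 0.83), the globins Hba-a1 (-3.69 ± 0.60) and Hbb-b1 (-3.62 ± 0.57) and the haem enzyme Alas2 (-3.69 ± 0.49). The list as a whole was not called and had 7 of 20 higher and 6 lower (8 and 6 adjusted over the list alone), a median of 0.12 against a mean of -0.44, and adjusted p = 0.312. Early lymphoid genes fell in 5 of 10 and rose in 1 (5 and 1 adjusted over the list alone; median -1.34, adjusted p = 0.0696). The receptors Flt3 (-2.53 ± 0.34) and Notch1 (-1.06 ± 0.12) were among them. B lymphoid genes fell in 4 of 9 (4 adjusted over the list alone; median -0.87, adjusted p = 0.243). Granulocyte and monocyte genes fell in 5 of 19 with 1 higher (5 and 1 adjusted over the list alone; median -0.71, adjusted p = 0.0958). The T and NK list had 2 of 5 higher (2 adjusted over the list alone; median -0.24, mean 0.25, adjusted p = 0.489), the chemokine Ccl5 and Nkg7. Megakaryocyte genes had 5 of 21 higher and 3 lower (5 and 3 adjusted over the list alone; median 0.13, adjusted p = 0.622). Endothelial and stromal genes had 1 of 8 higher and 2 lower (1 and 0 adjusted over the list alone; median -0.16, with a positive camera direction, adjusted p = 0.947).

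Genes that respond to acute stimulation were low after pegIFN in wild-type cells. Immediate early genes fell in 16 of 19 (17 adjusted over the list alone; median -1.77, adjusted p = 4.3e-05). Nr4a1 (-3.35 ± 0.70, adjusted p = 0.0004), Egr1 (-2.49 ± 0.41, adjusted p = 3.5e-05) and Ier3 (-1.36 ± 0.12) were among them. NF-kB and inflammatory genes fell in 9 of 18 and rose in 1 (9 and 1 adjusted over the list alone; median -0.48, adjusted p = 0.0395). The adhesion molecule Icam1 (-1.26 ± 0.11) and Nfkbiz (-2.04 ± 0.28) were among them. Of the chaperones, 7 of 11 heat shock genes were higher (7 adjusted over the list alone; median 0.73, adjusted p = 0.00325), among them the mitochondrial pair Hspd1 (0.76 ± 0.09) and Hspe1 (0.90 ± 0.12). The exact permutation of mice ended this list call (adjusted p = 0.0543). The unfolded protein and integrated stress list had 10 of 16 higher and 2 lower (10 and 2 adjusted over the list alone; median 0.47, adjusted p = 0.0276). The stress factor Ddit3 was at 0.80 ± 0.10 and the chaperone Dnajb9 at -0.89 ± 0.11. Each of these lists had adjusted p = 0.559 with an estimated correlation.

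Nuclear and mitochondrial genes of respiration went opposite ways in wild-type cells. Of 38 nuclear genes of oxidative phosphorylation, 36 rose and none fell (36 and 0 adjusted over the list alone; median 0.39, adjusted p = 1.0e-07). Sdhb (0.69 ± 0.08) and Ndufs7 (0.63 ± 0.07) were among them. All 13 genes encoded by mitochondrial DNA fell (13 adjusted over the list alone; median -0.69, adjusted p = 0.0006). The transcript mt-Co3 was at -0.69 ± 0.12 and mt-Cytb at -0.71 ± 0.12. Both lists had adjusted p = 0.559 with an estimated correlation. Lists not called were glycolysis and hypoxia (7 of 17 higher, 3 lower, 7 and 3 adjusted over the list alone, median 0.12, adjusted p = 0.306) and haem and iron handling (5 of 13 higher, 2 lower, 5 and 2 adjusted over the list alone, median -0.07, mean 0.05, adjusted p = 0.68). The same held for cholesterol synthesis (6 of 15 higher, 1 lower, 8 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.113) and JAK2-STAT5 targets (7 of 15 higher, 5 lower, 7 and 5 adjusted over the list alone, median 0.34, mean -0.12, adjusted p = 0.689). The 4 Y-linked genes fell in the wild-type comparison (4 adjusted over the list alone; median -2.59, adjusted p = 0.0214, and adjusted p = 0.559 with an estimated correlation), in which wild-type vehicle replicate 4 had high Y-linked counts. The other 5 wild-type vehicle libraries held 9.1 to 34.1% of the Jak2V617F vehicle mean for these genes and the 6 wild-type pegIFN libraries held 1 to 10.2%.

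In this comparison 9027 of 15879 genes were called, 4474 higher and 4553 lower, and 2128 of them changed at least 2-fold, 425 higher and 1703 lower. Under upper-quartile factors 39.3% of the called genes were higher, against 49.6% with the main scaling, so the balance of directions depends on the scaling. Over the 5 comparisons fitted without a block, the list calls that hold with an estimated correlation are those of interferon-stimulated genes in both interferon comparisons and of Y-linked genes between genotypes under pegIFN.

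The same comparison in Jak2V617F LT-HSCs, the cells the study's title concerns, showed an interferon response of similar size. Interferon-stimulated genes rose in 51 of 52 and fell in 1 (51 and 1 adjusted over the list alone; median 2.53, adjusted p = 5.7e-313). Ifi27l2a was at 6.81 ± 0.15, Mx1 at 5.99 ± 0.28 and Irf7 at 5.13 ± 0.16. Isg15 went from 5.60 ± 0.680 to 187 ± 23.1 CPM (log2 5.06 ± 0.11, adjusted p = 1.1e-21). Interferon-inducible GTPases rose in 12 of 16 and fell in 1 (12 and 1 adjusted over the list alone; median 0.84, adjusted p = 0.00029, and adjusted p = 0.548 with an estimated correlation). Class I antigen presentation rose in 16 of 19 and fell in 1 (17 and 1 adjusted over the list alone; median 0.51, adjusted p = 2.4e-09, and adjusted p = 0.335 with an estimated correlation). H2-T22 was at 1.18 ± 0.10 and the light chain B2m at 0.65 ± 0.09. Receptor and JAK-STAT components were higher in 3 of 20 and lower in 6 (3 and 6 adjusted over the list alone; median -0.10, adjusted p = 0.194). Ifnar1 was at -0.32 ± 0.06 and Jak1 at -0.28 ± 0.05, and Jak2 was at 0.09 ± 0.07 (adjusted p = 0.28).

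Apoptosis genes and p53 targets of Jak2V617F cells also changed with pegIFN. Bax rose from 44.7 ± 3.48 to 79.6 ± 9.85 CPM (log2 0.83 ± 0.07, adjusted p = 2.8e-09) and Bak1 by 0.46 ± 0.06 (adjusted p = 1.7e-06). Bcl2l1 rose from 60.8 ± 10.8 to 88.8 ± 6.74 CPM (log2 0.55 ± 0.11, adjusted p = 0.00042). Mcl1 fell by 0.51 ± 0.10 (adjusted p = 0.00022), and Bcl2 was at -0.14 ± 0.08 (adjusted p = 0.16). Bbc3 rose by 0.67 ± 0.17 (adjusted p = 0.0025), Bmf fell by 1.40 ± 0.34, and Pmaip1 (0.45 ± 0.31, adjusted p = 0.24) and Bcl2l11 (-0.21 ± 0.09, adjusted p = 0.052) were not called. The pro-apoptotic list had 4 of 10 higher and 2 lower (5 and 3 adjusted over the list alone; median 0.37, adjusted p = 0.127). The pro-survival list had 1 of 5 higher and 2 lower (1 and 2 adjusted over the list alone; median -0.14, adjusted p = 0.618). The death receptor and caspase list had 7 of 27 higher and 8 lower (7 and 8 adjusted over the list alone; median 0.03, of unsteady sign between scalings, adjusted p = 0.223). Targets of p53 rose in 11 of 20 and fell in 1 (13 and 1 adjusted over the list alone; median 0.64, adjusted p = 2.6e-05, and adjusted p = 0.335 with an estimated correlation). Cdkn1a rose from 11.0 ± 5.12 to 29.5 ± 11.4 CPM (log2 1.42 ± 0.32, adjusted p = 0.0012). Phlda3 rose by 2.40 ± 0.31 (adjusted p = 2.4e-06), the receptor Eda2r by 1.69 ± 0.27 and the stress sensor Sesn2 by 0.82 ± 0.12 (adjusted p = 5.8e-06).

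Replication genes of Jak2V617F cells rose in 14 of 21 (16 adjusted over the list alone; median 0.29, adjusted p = 0.00054, and adjusted p = 0.549 with an estimated correlation). Mcm5 was at 0.42 ± 0.09 and Cdt1 at 0.42 ± 0.08. Mitotic genes had 0 of 22 higher and 1 lower in edgeR, the spindle protein Nusap1 at -0.42 ± 0.15 (0 and 0 adjusted over the list alone; median 0.03, of unsteady sign between scalings, adjusted p = 0.934). DNA repair genes had 3 of 22 higher (3 adjusted over the list alone; median 0.10, adjusted p = 0.211). Stem cell identity genes fell in 19 of 23 and rose in 1 (19 and 1 adjusted over the list alone; median -0.77, adjusted p = 2.7e-06, and adjusted p = 0.335 with an estimated correlation). Sult1a1 fell by 3.53 ± 0.31 and Fgd5 fell by 2.55 ± 0.32, and, picked after their values were seen, Procr fell by 1.46 ± 0.30 and Hlf fell by 1.38 ± 0.27. Ly6a rose from 53.2 ± 10.5 to 263 ± 70.9 CPM and, picked after its values were seen, Cd48 from 12.4 ± 1.87 to 33.0 ± 6.02 CPM (log2 1.42 ± 0.19, adjusted p = 3.1e-06). Quiescence regulators fell in 12 of 16 and rose in 1, Cdkn1a (12 and 1 adjusted over the list alone; median -0.43, adjusted p = 0.00066, and adjusted p = 0.261 with an estimated correlation). Cdkn1c was at -1.22 ± 0.22 and Foxo1 at -0.48 ± 0.08.

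The erythroid list of Jak2V617F cells again held members that rose (8 of 20) and fell (6; 9 and 7 adjusted over the list alone; median 0.41, mean -0.49, adjusted p = 0.585). Klf1 was at 1.44 ± 0.25 and Gata1 at 0.91 ± 0.15 against Slc4a1 at -4.90 ± 0.87 and Hba-a1 at -3.50 ± 0.60. Immediate early genes fell in 14 of 19 (15 adjusted over the list alone; median -1.36, adjusted p = 4.0e-05). Heat shock genes rose in 7 of 11 (7 adjusted over the list alone; median 0.64, adjusted p = 0.00081, and adjusted p = 0.127 in the exact permutation). The unfolded protein list was higher in 10 of 16 and lower in 1 (11 and 1 adjusted over the list alone; median 0.39, adjusted p = 0.0049). Cholesterol synthesis rose in 12 of 15 (13 adjusted over the list alone; median 0.39, adjusted p = 0.0035). The enzymes Fdps (0.73 ± 0.10) and Sqle (0.39 ± 0.07) were among them. Nuclear respiration genes rose in 34 of 38 (35 adjusted over the list alone; median 0.31, adjusted p = 3.2e-07), with Sdhb at 0.52 ± 0.08. Each of these called lists had adjusted p = 0.548 with an estimated correlation. Mitochondrial-encoded genes fell in 1 of 13 (0 adjusted over the list alone; median -0.19, adjusted p = 0.185), mt-Cytb at -0.33 ± 0.12 (adjusted p = 0.027). The immediate early gene Fos lay at 107.97 to 194.5 CPM in both genotypes of pegIFN mice P10, P40 and P50 and at 344.56 to 694.24 CPM in P30, P52 and P53.

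Further lists not called in Jak2V617F cells were NF-kB (8 of 18 lower, 8 adjusted over the list alone, median -0.30, adjusted p = 0.0717) and early lymphoid genes (5 of 10 lower, 5 adjusted over the list alone, median -0.80, adjusted p = 0.109). Endothelial and stromal genes were not called either (4 of 8 lower, 4 adjusted over the list alone, median -0.91, adjusted p = 0.314). The Y-linked (0 of 4 called by edgeR, median -0.30, adjusted p = 0.619) and granulocyte and monocyte lists (1 of 19 higher, 2 lower, 1 and 1 adjusted over the list alone, median -0.39, adjusted p = 0.616) were likewise not called. So were B lymphoid genes (1 of 9 lower, 0 adjusted over the list alone, median -1.02, adjusted p = 0.616) and the T and NK list (2 of 5 higher, 2 higher and 1 lower adjusted over the list alone, median 0.86, mean 0.54, adjusted p = 0.223). Megakaryocyte genes had 2 of 21 higher and 2 lower (1 and 2 adjusted over the list alone; median 0.12, adjusted p = 0.59), and glycolysis and hypoxia had 5 of 17 higher and 2 lower (5 and 2 adjusted over the list alone; median 0.10, adjusted p = 0.173). Haem and iron handling had 4 of 13 higher and 2 lower (4 and 2 adjusted over the list alone; median 0.14, adjusted p = 0.305). JAK2-STAT5 targets had 7 of 15 higher and 3 lower (7 and 4 adjusted over the list alone; median 0.05, of unsteady sign between scalings, adjusted p = 0.505).

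In Jak2V617F cells 6991 genes were called, 3446 higher and 3545 lower, and 1419 changed at least 2-fold, 328 higher and 1091 lower. Under upper-quartile factors 38.8% of the called genes were higher, against 49.3% with the main scaling. Both genotypes called 6254 genes in the same direction, 3103 higher and 3151 lower, and 4 genes in opposite directions. Both comparisons use libraries of the same 12 mice, and other assignments of the mice to treatment gave at most 3612 genes in the same direction. The assignment with 3612 kept 5 of the 6 pegIFN mice in place.

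**Figure D4:**
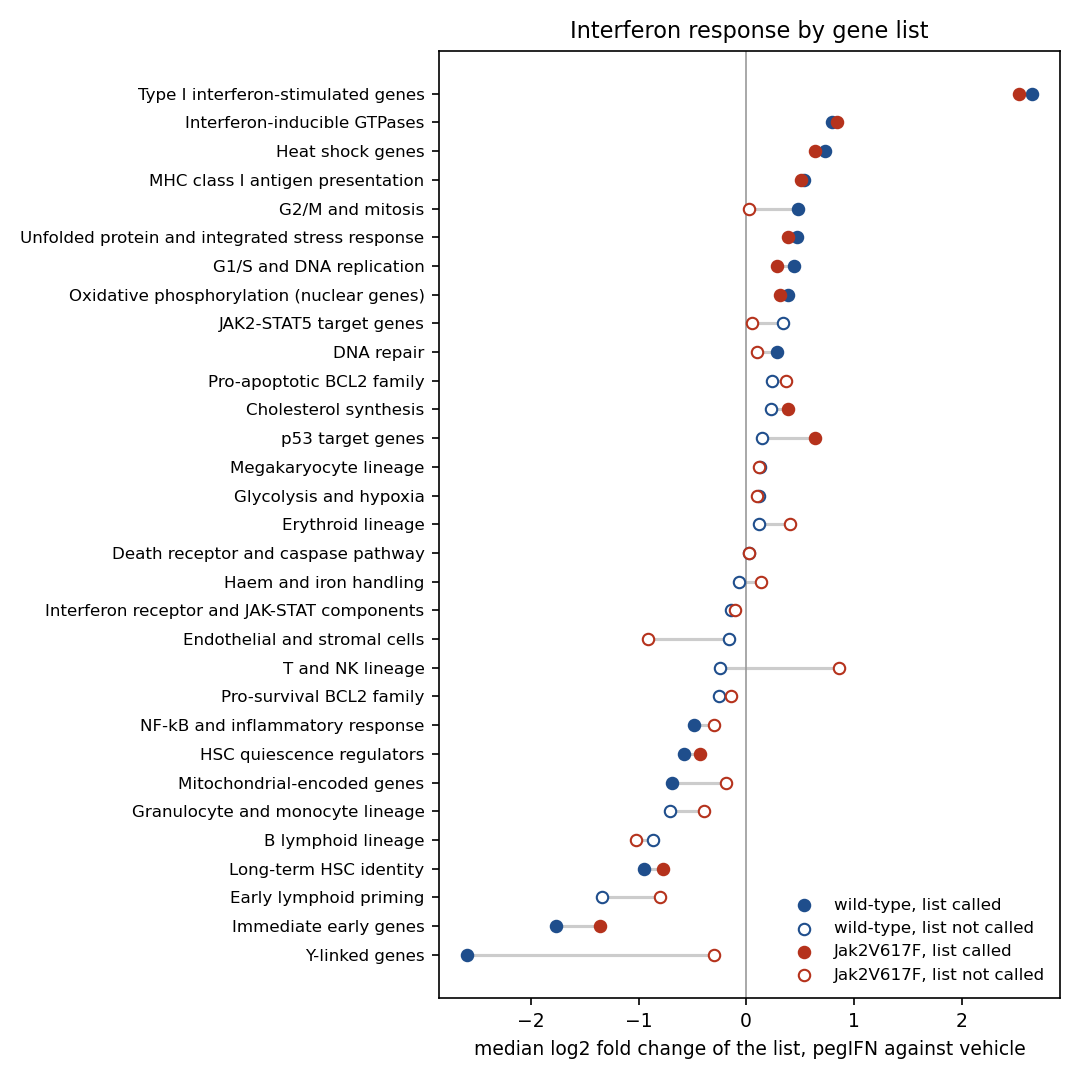
Median log2 fold change with pegIFN of each of 31 gene lists in wild-type (blue) and Jak2V617F (red) cells, filled where camera with a preset correlation called the list. Interferon-stimulated genes lie at 2.65 and 2.53, while the p53 list lies at 0.15 in wild-type and 0.64 in Jak2V617F cells and the G2/M list at 0.48 and 0.03, the last a median whose sign turns with the scaling.

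The third comparison, Jak2V617F against wild-type cells under vehicle, asks how the mutant cells differ without treatment. Apart from the pair of libraries above, sex-linked genes run together with the genotype, as does the CD45 donor marker. The mutation, donor sex and donor background therefore cannot be told apart in any comparison of the genotypes. Mitotic genes were higher in Jak2V617F cells in 22 of 22 (22 adjusted over the list alone; median 0.63, adjusted p = 2.7e-27, and adjusted p = 0.263 with an estimated correlation). Ube2c, which directs the degradation of mitotic proteins, was at 81.8 ± 11.98 against 42.4 ± 10.5 CPM (log2 0.95 ± 0.12, adjusted p = 0.00012). The cyclin Ccnb1 was at 0.86 ± 0.12 (adjusted p = 0.00038), the survivin gene Birc5 at 0.73 ± 0.12 (adjusted p = 0.0012) and Cdk1 at 0.69 ± 0.12 (adjusted p = 0.0017). Replication genes were higher in 3 of 21 (4 adjusted over the list alone; median 0.22, adjusted p = 4.5e-06, and adjusted p = 0.651 with an estimated correlation). Tyms was at 0.44 ± 0.10. All 21 were higher with the mouse as a block. DNA repair genes were higher in 7 of 22 and lower in 1 (11 and 1 adjusted over the list alone; median 0.21, adjusted p = 0.00014, and adjusted p = 0.651 with an estimated correlation). Fanca was at 0.57 ± 0.13. The blocked fit called 16 higher. Nuclear respiration genes were higher in 32 of 38 (35 adjusted over the list alone; median 0.31, adjusted p = 8.5e-22, and adjusted p = 0.335 with an estimated correlation). Cox5a was at 0.54 ± 0.11 and Ndufb8 at 0.43 ± 0.08.

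Stem cell identity genes were lower in Jak2V617F cells under vehicle in 6 of 23 (6 adjusted over the list alone; median -0.31, adjusted p = 4.0e-06, and adjusted p = 0.335 with an estimated correlation), 14 with the mouse as a block. The stem cell factor receptor Kit was at -0.60 ± 0.13 (adjusted p = 0.0071), Sult1a1 at -1.37 ± 0.26 (adjusted p = 0.0031) and Meis1 at -0.27 ± 0.06 (adjusted p = 0.0066). Quiescence regulators were lower in 6 of 16 (6 lower and 1 higher adjusted over the list alone; median -0.30, adjusted p = 0.0008, and adjusted p = 0.263 with an estimated correlation). Foxo1 was at -0.46 ± 0.08, Foxo3 at -0.34 ± 0.07 and Txnip at -0.73 ± 0.17. Megakaryocyte genes were higher in 3 of 21 and lower in 2 (3 and 2 adjusted over the list alone; median 0.25, adjusted p = 0.0397, and adjusted p = 0.895 with an estimated correlation), and in 10 and 2 with the mouse as a block. The platelet chemokine Pf4 was at 1.09 ± 0.32 (adjusted p = 0.031) and the platelet receptor subunit Gp1bb at 0.79 ± 0.25.

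The granulocyte and monocyte list had a higher median in Jak2V617F cells under vehicle. In edgeR 0 of 19 granulocyte and monocyte genes were called in either direction (0 adjusted over the list alone), their median was 1.08 (adjusted p = 0.0028, and adjusted p = 0.835 with an estimated correlation), and 6 were higher with the mouse as a block. The neutrophil elastase gene Elane ran at 109 ± 77.4 against 38.2 ± 26.5 CPM (log2 1.51 ± 0.51, adjusted p = 0.055), with Jak2V617F vehicle libraries from 20.95 to 223.07 CPM. Of the largest increases, Alox5 (1.37 ± 0.23, adjusted p = 0.0021), the leukotriene enzyme of myeloid cells, Thbs1 (1.30 ± 0.36), a protein of platelet granules, and Ms4a3 (1.08 ± 0.34), a marker of myeloid progenitors, passed the test.

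Interferon-stimulated genes were slightly lower in untreated Jak2V617F cells, in 9 of 52 with 1 higher (15 and 1 adjusted over the list alone; median -0.15, adjusted p = 0.00017, and adjusted p = 0.771 with an estimated correlation), 23 and 4 with the mouse as a block. Trim30a was at -0.37 ± 0.07, Rsad2, known as viperin, at -0.42 ± 0.11, and Isg15 was higher at 0.37 ± 0.11 (adjusted p = 0.034). Receptor and JAK-STAT components were lower in 5 of 20 (7 lower and 1 higher adjusted over the list alone; median -0.15, adjusted p = 0.0113, and adjusted p = 0.593 with an estimated correlation), 11 lower and 2 higher with the mouse as a block. The lower genes held Jak1 (-0.23 ± 0.05), Jak2 (-0.22 ± 0.07, adjusted p = 0.033) and Ifnar1 (-0.22 ± 0.06). Interferon-inducible GTPases, 0 of 16 called in edgeR (median -0.25, adjusted p = 0.18), were called as a list with the mouse as a block (adjusted p = 0.0317, and adjusted p = 0.723 with an estimated correlation). Heat shock genes were higher in 2 of 11 (2 adjusted over the list alone; median 0.29, adjusted p = 0.0391, and adjusted p = 0.835 with an estimated correlation), 8 with the mouse as a block. The unfolded protein list was higher in 5 of 16 with 1 lower (5 and 1 adjusted over the list alone; median 0.23, adjusted p = 0.0288, and adjusted p = 0.771 with an estimated correlation), 10 and 1 with the mouse as a block.

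Of the apoptosis genes under vehicle, Bax (0.36 ± 0.07, adjusted p = 0.0037) and Bak1 (0.19 ± 0.06, adjusted p = 0.038) were higher in Jak2V617F cells. Bcl2l1 was at 0.21 ± 0.11 (adjusted p = 0.21) and was called with the mouse as a block (0.21 ± 0.05, adjusted p = 0.0029). Blocked calls also arose for Pmaip1 (0.48 ± 0.14, adjusted p = 0.016), Bbc3 (-0.32 ± 0.10, adjusted p = 0.023) and Bcl2l11 (-0.20 ± 0.07, adjusted p = 0.038). Mcl1 (-0.09 ± 0.10, adjusted p = 0.57) and Bcl2 (0.00 ± 0.08, adjusted p = 0.98) were not called. Cdkn1a ran at 11.0 ± 5.12 against 10.7 ± 4.64 CPM (log2 0.04 ± 0.32, adjusted p = 0.95). The p53 list had 3 of 20 higher (4 adjusted over the list alone; median 0.06, adjusted p = 0.379), Bax, Rps27l and Gtse1.

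Under vehicle 2018 genes were called, 1346 higher and 672 lower in Jak2V617F cells, 113 of them at least 2-fold. With the mouse as a block the count was 4944, 2779 higher and 2165 lower, with 215 at least 2-fold, and it held 2010 of the 2018. Without the pair of libraries that stood apart on sex-linked genes, left out after the data were seen, it was 999. The count was 929 without wild-type vehicle replicate 4, 1107 without replicate 5 and 1309 without replicate 6 of that group. It was 1334 without Jak2V617F vehicle replicate 1 and 1337 without replicate 3. Under upper-quartile factors 54.7% of the called genes were higher, against 66.7% with the main scaling. An exact permutation of the sign of each of the 6 mice, added after the data were seen, called none of the 31 lists (smallest p it can give 0.0312, adjusted p = 0.108). A list at that p passes the adjustment only where many other lists reach it too. The test therefore could not call a list by itself, and its 0 calls do not decide any of them. Genes within 10 Mb of Ptprc (ENSMUSG00000026395, chromosome 1, 138062861 to 138175305), the CD45 gene by which the donors were told apart, were called in 28 of 102 (27.5%) against 12.7% of other autosomal genes (odds ratio 2.59, Fisher's exact test, two-sided, p = 7.2e-05). With the mouse as a block the same 102 genes were called in 45 (44.1%) against 31.3% (odds ratio 1.73, Fisher's exact test, two-sided, p = 0.0072). Among the genes near Ptprc the protease gene Ctse (ENSMUSG00000004552, chromosome 1, 131638306 to 131675503) was at -2.64 ± 0.29 (adjusted p = 5.7e-05). Ptprc itself was at -0.25 ± 0.11 (adjusted p = 0.12), called with the mouse as a block (adjusted p = 0.0061).

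The fourth comparison, Jak2V617F against wild-type cells in mice given pegIFN, asks how the mutant cells differ under treatment. Targets of p53 were higher in Jak2V617F cells in 10 of 20 and lower in none (15 and 0 adjusted over the list alone; median 0.43, adjusted p = 2.0e-10, and adjusted p = 0.122 with an estimated correlation). The blocked fit called 17 of 20 higher, and in it the estimated correlation gave adjusted p = 0.00128. Cdkn1a ran at 29.5 ± 11.4 against 12.7 ± 3.27 CPM (log2 1.22 ± 0.32, adjusted p = 0.022), with Jak2V617F libraries from 17.93 to 50.65 and wild-type libraries from 8.85 to 18.08 CPM. Bax was at 79.6 ± 9.85 against 60.2 ± 2.56 CPM (log2 0.40 ± 0.07, adjusted p = 0.0013). Pmaip1, the BH3-only gene that opposes Mcl1, was at 4.24 ± 1.68 against 2.05 ± 0.643 CPM (log2 1.05 ± 0.31, adjusted p = 0.039). Eda2r (9.19 ± 2.78 against 4.27 ± 1.37 CPM, adjusted p = 0.013), Rps27l (0.60 ± 0.11, adjusted p = 0.0015) and Ccng1 (0.37 ± 0.11, adjusted p = 0.034) were higher too.

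Of the survival genes under pegIFN, Bcl2l1 was at 88.8 ± 6.74 against 74.0 ± 7.60 CPM (log2 0.26 ± 0.11, adjusted p = 0.15; 0.26 ± 0.05, adjusted p = 0.00081 with the mouse as a block). Mcl1 was at 0.13 ± 0.10 (adjusted p = 0.45; 0.14 ± 0.04, adjusted p = 0.013 with the mouse as a block) and Bcl2 at 0.12 ± 0.08 (adjusted p = 0.36). Bak1 (0.08 ± 0.06, adjusted p = 0.43), Bbc3 (0.20 ± 0.17, adjusted p = 0.51) and Bcl2l11 (-0.09 ± 0.09, adjusted p = 0.6) were not called. Cycs, the cytochrome c gene, was higher at 0.35 ± 0.11 (adjusted p = 0.041).

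The granulocyte and monocyte list also had a higher median in Jak2V617F cells under pegIFN. Of 19 granulocyte and monocyte genes, 7 were higher and none lower (13 and 0 adjusted over the list alone; median 1.27, adjusted p = 1.7e-11, and adjusted p = 0.346 with an estimated correlation), 16 with the mouse as a block. The list mean was higher in all 6 mice. The exact permutation gave the smallest p it can give (adjusted p = 0.0646), which cannot decide the call of a single list. Elane ran at 124 ± 33.8 against 31.9 ± 16.8 CPM (log2 1.96 ± 0.52, adjusted p = 0.025). Prtn3 was at 1.27 ± 0.27 and Ctsg at 2.02 ± 0.49. The myeloid genes Retnlg (2.41 ± 0.63, adjusted p = 0.023), Slfn4 (2.37 ± 0.65, adjusted p = 0.029) and Ccl6 (2.03 ± 0.51, adjusted p = 0.019) were among the 8 largest increases. Gfi1, a factor of neutrophil development, was at 1.16 ± 0.27. Megakaryocyte genes, 0 of 21 called in edgeR (0 adjusted over the list alone; median 0.20, adjusted p = 0.0338, and adjusted p = 0.675 with an estimated correlation), were higher in 6 with the mouse as a block. Erythroid genes were lower in 2 of 20 (3 adjusted over the list alone; median -0.11, adjusted p = 0.027, and adjusted p = 0.675 with an estimated correlation), 8 lower and 1 higher with the mouse as a block. Mouse P40 stood apart, with a difference in mean log2 CPM of the list of -1.128, Jak2V617F minus wild-type, against -0.238 to 0.157 in the other 5 mice. The water channel Aqp1 was at -0.91 ± 0.14 and Car1 at -1.18 ± 0.37.

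Respiration genes of both genomes were higher in Jak2V617F cells under pegIFN. Mitochondrial-encoded genes were higher in 12 of 13 (13 adjusted over the list alone; median 0.53, adjusted p = 2.7e-11, and adjusted p = 0.346 with an estimated correlation). The transcript mt-Co3 was at 2490 ± 496 against 1759 ± 181 CPM (log2 0.50 ± 0.11, adjusted p = 0.0099). Nuclear genes were higher in 16 of 38 (25 adjusted over the list alone; median 0.22, adjusted p = 1.5e-12, and adjusted p = 0.5 with an estimated correlation), 33 with the mouse as a block. Ndufv2 was at 0.37 ± 0.09. Mitotic genes were higher in 1 of 22 (4 adjusted over the list alone; median 0.16, adjusted p = 0.0035, and adjusted p = 0.675 with an estimated correlation), 7 with the mouse as a block. The member called in edgeR was Cdk1 at 0.38 ± 0.12 (adjusted p = 0.043). The unfolded protein list had 1 of 16 higher, Sesn2 (3 adjusted over the list alone; median 0.19, adjusted p = 0.0177, and adjusted p = 0.585 with an estimated correlation), 9 higher and 1 lower with the mouse as a block. Glycolysis had 1 of 17 higher and 1 lower (4 and 1 adjusted over the list alone; median 0.13, adjusted p = 0.0469, and adjusted p = 0.585 with an estimated correlation), 8 and 1 with the mouse as a block.

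Interferon-stimulated genes were again slightly lower in Jak2V617F cells, in 8 of 52 with 1 higher (11 and 1 adjusted over the list alone; median -0.12, adjusted p = 0.00014, and adjusted p = 0.585 with an estimated correlation), 24 and 2 with the mouse as a block. The sensor Ifih1 (-0.33 ± 0.07) and Rnf213 (-0.44 ± 0.09) were lower. Signalling components were lower in 5 of 20 and higher in 1 (6 and 1 adjusted over the list alone; median -0.07, adjusted p = 0.0035, and adjusted p = 0.457 with an estimated correlation). The interferon gamma receptor Ifngr1 was at -0.73 ± 0.11 (adjusted p = 0.0003), Stat5a at -0.32 ± 0.07, Stat5b at -0.36 ± 0.06 and Jak2 at -0.30 ± 0.07 (adjusted p = 0.0091). Quiescence regulators were lower in 5 of 16 and higher in 2 (5 and 2 adjusted over the list alone; median -0.09, adjusted p = 0.0471, and adjusted p = 0.5 with an estimated correlation), a call that ended with the mouse as a block (adjusted p = 0.169). Foxo3 was lower at -0.41 ± 0.07, and Gfi1 and Cdkn1a were higher. Kit was at -0.60 ± 0.13 (adjusted p = 0.0094). Lists called only with the mouse as a block were immediate early genes (median 0.26 without the block, adjusted p = 4.1e-05 with it), heat shock (0.16, adjusted p = 0.0016) and class I antigen presentation (-0.08, adjusted p = 0.015). Further such lists were G1/S (0.06, adjusted p = 0.0168), stem cell identity (-0.08, adjusted p = 0.0261) and JAK2-STAT5 targets (0.17, adjusted p = 0.0495). With an estimated correlation in the blocked fit none of these 6 lists was called (adjusted p = 0.261 to 0.494).

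The largest decreases in Jak2V617F cells under pegIFN, after Xist, were Ctse (-3.01 ± 0.30, adjusted p = 4.3e-06), the kinase-like regulator Trib2 (-2.36 ± 0.29, adjusted p = 4.6e-05) and Scin (14.3 ± 3.26 against 65.5 ± 20.5 CPM, log2 -2.19 ± 0.49, adjusted p = 0.0099). They were followed by the phosphatase Ptpn14 (-2.10 ± 0.23), the receptor Pdgfrb (-1.77 ± 0.23), the interleukin-33 receptor Il1rl1 (-1.60 ± 0.31, adjusted p = 0.0041) and Slc45a3 (-1.43 ± 0.42, adjusted p = 0.04). Genes within 10 Mb of Ptprc were called in 17 of 102 (16.7%) against 8.4% of other autosomal genes (odds ratio 2.17, Fisher's exact test, two-sided, p = 0.0065), and with the mouse as a block in 36 (35.3%) against 24.5% (odds ratio 1.68, p = 0.0152).

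Under pegIFN 1364 genes were called, 661 higher and 703 lower in Jak2V617F cells, 198 of them at least 2-fold. With the mouse as a block the count was 3910, 2109 higher and 1801 lower, with 338 at least 2-fold, and it held all 1364. Without the pair of libraries that stood apart on sex-linked genes it was 653. The count was 851, 677, 883, 701 and 767 without wild-type pegIFN replicates 1, 2, 3, 4 and 5. It was 593, 2051, 692 and 794 without Jak2V617F pegIFN replicates 1, 3, 4 and 6. The balance of directions was not steady: 364 higher and 609 lower with no filter, 216 and 461 without wild-type pegIFN replicate 2, and 167 and 426 without Jak2V617F pegIFN replicate 1. The exact permutation over the 6 mice called none of the 31 lists here either, with 15 at the smallest p it can give, 0.0312 (adjusted p = 0.0646). As under vehicle, it could not call a list by itself.

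The last comparison, the interaction, asks whether interferon acts differently in the mutant cells. In edgeR without a block 0 genes were called (smallest adjusted p = 0.0684, 1338 genes at an unadjusted p under 0.05). DESeq2 called 47 (12 higher and 35 lower), limma-voom with the mouse as a random block 290. The blocked fit in edgeR called 528, 203 with a positive and 325 with a negative interaction. The count without a block was 9 without wild-type pegIFN replicate 3, 36 without wild-type pegIFN replicate 6, 3 without Jak2V617F pegIFN replicate 1, and 1 without Jak2V617F vehicle replicate 4, 5 or 6. The blocked count was 104 without the mice of the pair of libraries that stood apart on sex-linked genes.

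Targets of p53 as a list rose more in Jak2V617F cells, with a median interaction of 0.47 (0 of 20 called over all genes and 5 higher adjusted over the list alone; adjusted p = 1.2e-07, and adjusted p = 0.304 with an estimated correlation). In the blocked fit 6 of 20 were called higher (adjusted p = 5.8e-13, and adjusted p = 0.00362 with an estimated correlation). The difference between the genotypes in mean log2 CPM of the list was 0.471 to 0.757 in the 6 pegIFN mice and -0.14 to 0.284 in the 6 vehicle mice. An exact permutation of the 12 mice, two-sided and added after the data were seen, gave p = 0.00216 for the difference of 0.48, the smallest it can give (adjusted p = 0.0224). The blocked fit called Cdkn1a (1.16 ± 0.12, adjusted p = 8.8e-05, against 1.18 ± 0.45, adjusted p = 0.52 without the block), Trp53inp1 (0.80 ± 0.10, adjusted p = 0.002) and Ccng1 (0.44 ± 0.07, adjusted p = 0.0055). It also called Sesn2 (0.60 ± 0.11, adjusted p = 0.012), Eda2r (1.28 ± 0.26, adjusted p = 0.015) and Btg2 (0.76 ± 0.15, adjusted p = 0.019). Whether list members lie near Ptprc or on a sex chromosome was not examined for the interaction. Donor background and donor sex are therefore not separated from the mutation for any of them. Trp53inp1 and Btg2 fell with pegIFN in wild-type cells, so their positive interactions do not stand for a larger rise in Jak2V617F cells. The named genes of the blocked fit were taken by the same rule after its values were seen.

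Mitotic genes had the larger response in wild-type cells, with a median interaction of -0.44 (0 of 22 called over all genes and 18 lower adjusted over the list alone; adjusted p = 1.4e-18, and adjusted p = 0.304 with an estimated correlation). The blocked fit called 18 of 22 lower. The difference between the genotypes in the list's mean was 0.061 to 0.235 in pegIFN mice and 0.323 to 0.993 in vehicle mice (difference -0.48, exact permutation, p = 0.00216, adjusted p = 0.0224). Among the vehicle mice it was 0.323 to 0.595 in V41, V42 and V43 and 0.769 to 0.993 in V44, V61 and V63. As with Fos, each mouse of one side shares its sample sheet position with a mouse of the other. In the blocked fit Ube2c was at -0.63 ± 0.11 (adjusted p = 0.0085), the centromere genes Cenpa at -0.60 ± 0.10 (adjusted p = 0.0069) and Cenpf at -0.49 ± 0.08 (adjusted p = 0.0085), and the proliferation marker Mki67 at -0.44 ± 0.09 (adjusted p = 0.02). Ube2c was at 69.5 ± 3.53 CPM in wild-type and 88.4 ± 9.20 CPM in Jak2V617F cells under pegIFN, against 42.4 ± 10.5 and 81.8 ± 11.98 CPM under vehicle.

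**Figure D5:**
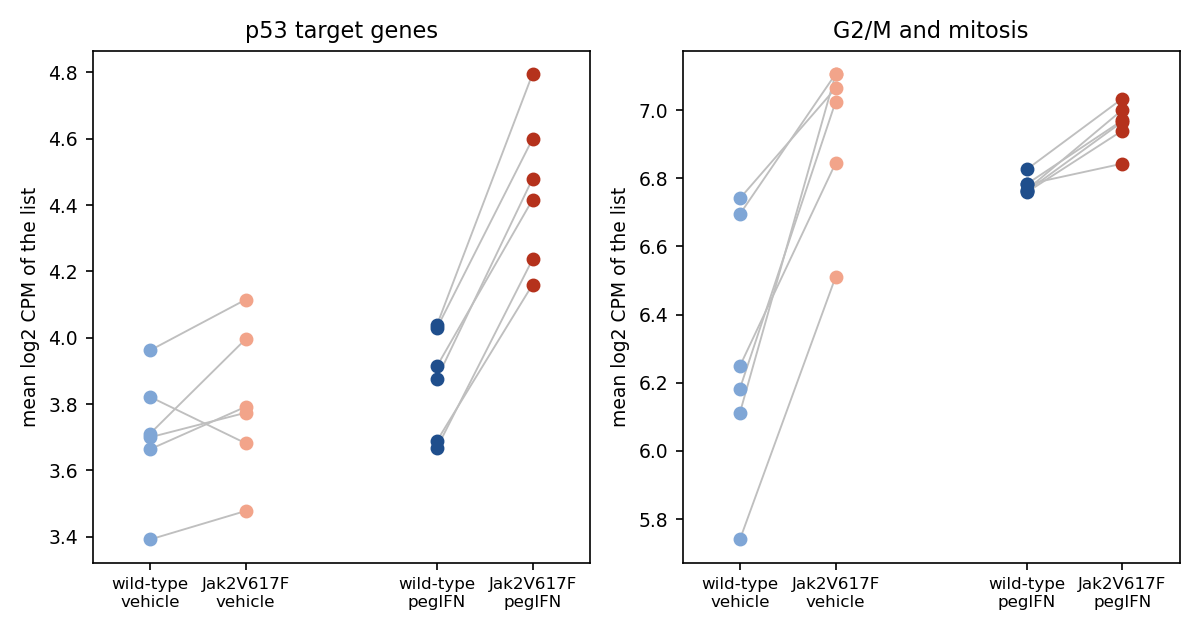
Mean log2 CPM of the p53 target list (left) and of the G2/M list (right), with a point for each library and lines joining the wild-type and Jak2V617F libraries of a mouse. The gap between genotypes in the p53 list is 0.471 to 0.757 in pegIFN mice and -0.14 to 0.284 in vehicle mice, and in the G2/M list 0.061 to 0.235 and 0.323 to 0.993.

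Of the apoptosis genes, Bcl2l1 (0.05 ± 0.16, adjusted p = 0.95; 0.05 ± 0.07, adjusted p = 0.73 with the mouse as a block) and Bax (0.05 ± 0.10, adjusted p = 0.91) had responses that the test did not separate between the genotypes. Mcl1 fell by less in Jak2V617F cells in the blocked fit (0.23 ± 0.05, adjusted p = 0.027, against 0.22 ± 0.14, adjusted p = 0.67 without the block). In the blocked fit Bbc3 (0.50 ± 0.14, adjusted p = 0.057) and Pmaip1 (0.53 ± 0.20, adjusted p = 0.15) were not called. Interferon-stimulated genes as a list had a median of 0.01 (adjusted p = 0.889), and Isg15 was called in the blocked fit (-0.39 ± 0.10, adjusted p = 0.032). Genes that rose far less in Jak2V617F cells in the blocked fit were Scin (-2.52 ± 0.41, adjusted p = 0.013), Trib2 (-1.81 ± 0.33, adjusted p = 0.019) and Slc45a3 (-1.79 ± 0.25, adjusted p = 0.0066). The same was true of Il1rl1 (-1.53 ± 0.30, adjusted p = 0.02), the lectin Siglec5 (-1.45 ± 0.20, adjusted p = 0.0034) and Ifngr1 (-0.66 ± 0.13, adjusted p = 0.016). Positions relative to Ptprc were not examined for these genes either. Meis1 (0.43 ± 0.06, adjusted p = 0.0035), Csf3r (0.96 ± 0.15, adjusted p = 0.0085), the receptor for granulocyte colony-stimulating factor, and the feedback inhibitor Socs3 (0.75 ± 0.13, adjusted p = 0.0085) fell by less.

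Other lists with a called interaction had no member called over all genes without the block. Mitochondrial-encoded genes had a median of 0.43 (8 higher adjusted over the list alone; adjusted p = 2.5e-09, and adjusted p = 0.463 with an estimated correlation), and Y-linked genes 2.29 (4 higher adjusted over the list alone; adjusted p = 3.1e-09, and adjusted p = 0.108 with an estimated correlation). Granulocyte and monocyte genes lay at 0.43 (adjusted p = 0.00049, and adjusted p = 0.714 with an estimated correlation) and endothelial and stromal genes -0.72 (3 lower adjusted over the list alone; adjusted p = 0.0113, and adjusted p = 0.516 with an estimated correlation). In the endothelial and stromal list the Jak2V617F vehicle replicate 4 library stood apart, with a mean log2 CPM 2.969 above its wild-type partner, against -0.467 to 0.824 in the other 5 vehicle mice. DNA repair (-0.16, adjusted p = 0.00013, and adjusted p = 0.603 with an estimated correlation), G1/S (-0.15, adjusted p = 0.002, and adjusted p = 0.725 with an estimated correlation) and nuclear respiration (-0.09, adjusted p = 0.003, and adjusted p = 0.818 with an estimated correlation) had the larger response in wild-type cells. Stem cell identity (0.18, 1 higher adjusted over the list alone, adjusted p = 0.002, and adjusted p = 0.603 with an estimated correlation), B lymphoid (0.35, adjusted p = 0.0346, and adjusted p = 0.603 with an estimated correlation) and immediate early genes (0.39, adjusted p = 0.0346, and adjusted p = 0.863 with an estimated correlation) had a positive median interaction. The mean log2 CPM of each of these lists fell with pegIFN in both genotypes, and by less in Jak2V617F cells. In the blocked fit quiescence regulators (adjusted p = 0.00132) and cholesterol synthesis (adjusted p = 0.0155) were called as well. Neither call held with an estimated correlation in that fit (adjusted p = 0.212 and adjusted p = 0.37) or in the exact permutation (adjusted p = 0.0537 and adjusted p = 0.134). NF-kB genes, not called by camera (median 0.06, adjusted p = 0.17), were separated by the exact permutation of mice (difference 0.27, p = 0.00216, adjusted p = 0.0224). The permutation ended all the calls without a block given in this paragraph: mitochondrial-encoded (adjusted p = 0.101), Y-linked (adjusted p = 0.054), granulocyte and monocyte (adjusted p = 0.218), endothelial and stromal (adjusted p = 0.318) and DNA repair genes (adjusted p = 0.089). For G1/S, nuclear respiration, stem cell identity, B lymphoid and immediate early genes it gave adjusted p = 0.218, adjusted p = 0.253, adjusted p = 0.318, adjusted p = 0.318 and adjusted p = 0.096.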

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

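The values of single libraries come from a rule fixed before the data were examined, by which 10 of 188 groups had a library far from the other 5, where 9.4 would by chance. Wild-type vehicle replicate 5 had a mean log2 CPM of 5.73 for JAK2-STAT5 targets (others 5.27 to 5.41). Wild-type pegIFN replicate 2 had 6.83 for G2/M genes (others 6.76 to 6.78). Jak2V617F pegIFN replicate 3 had 5.46 for stem cell identity genes (others 4.51 to 4.77). Wild-type pegIFN replicate 5 had 0.96 for endothelial and stromal genes (others 1.21 to 1.34). Wild-type vehicle replicate 6 had 5.61 for immediate early genes (others 7.14 to 7.69). Wild-type pegIFN replicate 1 had -0.98 for Y-linked genes (the others were positive, up to 2.16). Wild-type vehicle replicate 4 had 4.92 for Bax (others 5.13 to 5.25). For Xist, Jak2V617F pegIFN replicate 1 had 9.35 (others 5.35 to 6.78), Jak2V617F vehicle replicate 4 had 1.61 (others 4.39 to 5.78) and wild-type vehicle replicate 4 had 9.23 (others 10.92 to 11.69).

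Responses that differed between the genotypes were tested through the interaction. With camera at a preset correlation the median interaction was 0.47 for p53 targets, -0.44 for G2/M, -0.15 for G1/S, -0.16 for DNA repair, 0.18 for stem cell identity and 0.43 for granulocyte and monocyte genes. It was 0.35 for B lymphoid, -0.72 for endothelial and stromal, 0.39 for immediate early, -0.09 for nuclear oxidative phosphorylation, 0.43 for mitochondrial-encoded and 2.29 for Y-linked genes. With the mouse as a block 528 genes had a called interaction.

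For the p53 targets, whose interaction median was 0.47, the tests on the pair of libraries and on granulocyte RNA were written before their values were seen and the test on donor sex after. Without the mice of the pair of libraries the median in the blocked fit was 0.50 (adjusted p = 0.0111 with an estimated correlation), and with granulocyte and monocyte RNA as a covariate it was 0.43 (adjusted p = 0.045 with an estimated correlation), with 0.30 to 0.50 when each mouse was left out, which argues against both as the cause of the median. With the covariate the estimated correlation lost the call in most of these fits, 7 of 12, with adjusted p = 0.0572 without mouse V61 to adjusted p = 0.108 without mouse P53. A sex difference that acts alike in both treatments cancels from the interaction, so the vehicle difference of 0.06 does not test it. A sex difference that needs interferon cannot be told apart from the genotype, because both run together in these libraries.

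Both tests on the loss of stem cell identity genes with the rise of Gata1, Klf1 and Epor were chosen after the result was seen. Across the 12 mice, centred within treatment, the means of the identity list without Ly6a and of the 3 regulators had r = -0.85 (permutation, two-sided, p = 0.00436), -0.97 within the 6 pegIFN mice and -0.45 within the 6 vehicle mice. This is the sign that progenitors entering the gate as Sca-1 rises would give, but a change of state within the cells would give it too. Scaling of the libraries is argued against by a median of -0.83 under upper-quartile factors. Surface marker data per cell would be needed to separate the first 2 readings.

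All tests on the pair of libraries out of place on sex-linked genes were chosen after the result was seen. On an axis of 7 genes near Ptprc (0 wild-type, 1 Jak2V617F), wild-type vehicle replicate 4 lay at 0.62, 0.67 from the mean of its own group, and Jak2V617F pegIFN replicate 1 at 0.98, 0.02 from its own. That median hides a shift of Ctse toward wild-type in the latter, 97.5 CPM against 24.6 to 39.1 in the other 5 libraries. The libraries thus differ on this axis and the genes split both ways within each, so cells of the other genotype and donor cells of both sexes cannot be told apart over both libraries. An exchange with the partner library is argued against by the partner of the vehicle mouse, which has 3 CPM of Xist.

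The splits of the libraries were chosen before their values were seen. For the genes called with interferon chance can be excluded to the extent of the splits tried, with the real grouping highest (1 of 100 in each genotype; 9027 against at most 6531 in wild-type and 6991 against at most 4450 in Jak2V617F cells), as for the overlap (1 of 100; 6254 against at most 3612). These highest other counts all came from the same split, which kept 5 of the 6 pegIFN mice under their own label. The interaction without a block had 0 genes in the real and in all 100 splits, and with the mouse as a block 528 against at most 314 (1 of 70). The 314 likewise came from a split with 5 of the 6 pegIFN mice in place. For the genotype another split gave more genes in each treatment, 3216 against 2018 under vehicle and 1533 against 1364 under pegIFN (2 of 100 each). Both of these splits kept 10 of 12 libraries under their own genotype, so they still carry most of the real grouping. The splits of single libraries ignore the mouse. Exchanges of genotype within mice, which keep the pairs, gave at most 0 against 2018 under vehicle and 156 against 1364 under pegIFN without a block (1 of 32 each), so chance can be excluded to the extent of the exchanges tried. They gave at most 634 against 4944 under vehicle and 1546 against 3910 under pegIFN with the mouse as a block (1 of 32 each). The counts of 156, 634 and 1546 came from exchanges of 1 mouse. For the number of lists called at the preset correlation chance cannot be excluded in 4 of 5 comparisons. As many lists were called in 25 of 100 splits for interferon in wild-type (15, highest other 18) and 57 in Jak2V617F cells (12, highest other 18). The figures were 43 for genotype under vehicle (13, highest other 21), 11 under pegIFN (13, highest other 21) and 3 for the interaction (12, highest other 13).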

How the results depend on the processing

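Fits without the pair of libraries or their mice and permutations of lists were chosen after results were seen. Of 7015 cases of named gene and setting, 6679 kept their call (signs of uncalled genes aside), 136 were stronger, 200 weaker and 0 reversed. Of 156 counts 109 kept and 47 moved. Genes called for genotype under vehicle, genotype under pegIFN and the interaction were 2018, 1364 and 0 in the main fit. They were 4944, 3910 and 528 with the mouse as a fixed block, 5297, 3909 and 290 with limma-voom and the mouse as a random block, and 3959, 2530 and 104 with the block but without the mice of the pair of libraries. Without that pair of libraries they were 999, 653 and 0. A fit of only the groups compared gave 1152 under vehicle and cannot be run for the interaction, which uses all 4 groups. DESeq2 gave 47 for the interaction, and 1 surrogate variable gave 2075 under pegIFN and 1 for the interaction. Leaving out a library gave 929 (wild-type vehicle replicate 4) to 2650 (wild-type vehicle replicate 3) under vehicle, 593 (Jak2V617F pegIFN replicate 1) to 2051 (Jak2V617F pegIFN replicate 3) under pegIFN and 0 (wild-type pegIFN replicate 1, among others) to 36 (wild-type pegIFN replicate 6) for the interaction. Lists called in the order interferon in wild-type, in Jak2V617F, genotype under vehicle, under pegIFN and interaction were 15, 12, 13, 13 and 12 in the main test, 1, 1, 0, 1 and 0 with an estimated correlation, 25, 19, 9, 6 and 0 with fry, and 16, 16, 0, 0 and 3 with the exact permutation. For the genotype the permutation could call a list only where many lists reached its smallest p together, so those counts of 0 decide no single list. The permutation ended the calls of GTPases (adjusted p = 0.054) and heat shock genes (adjusted p = 0.054) in wild-type cells and of heat shock genes in Jak2V617F cells (adjusted p = 0.13). In wild-type cells it added the pro-apoptotic (adjusted p = 0.0052), pro-survival (adjusted p = 0.0089) and early lymphoid lists (adjusted p = 0.0089). In Jak2V617F cells it added NF-kB (adjusted p = 0.017), Y-linked (adjusted p = 0.028), receptor and JAK-STAT (adjusted p = 0.031), glycolysis (adjusted p = 0.031) and early lymphoid genes (adjusted p = 0.042). For the interaction it kept p53 targets and G2/M, added NF-kB and ended the other 10 calls. Across treatments libraries with the same replicate number come from different mice (r from -0.24 to 0.06), and a block by that number gave 9174 and 7207 genes for interferon.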

Other observations

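A pair of genes picked after their values were seen rose strongly with interferon in both genotypes. Carbonic anhydrase Car1, a member of the erythroid list, rose by 3.04 ± 0.39 in wild-type (adjusted p = 1.9e-06) and by 1.88 ± 0.38 in Jak2V617F cells (adjusted p = 0.00047). The thrombospondin gene Thbs1, in none of the lists, rose by 2.41 ± 0.36 in wild-type (adjusted p = 9.6e-06) and by 1.79 ± 0.35 in Jak2V617F cells (adjusted p = 0.00033).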
